A study of Bos taurus with 36 samples.

How the data were processed

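Per the labels, total RNA of granulosa cells (PicoPure) went through 2 rounds of T7 amplification (RiboAmp HS Plus) and was labelled with Cy3 or Cy5 (ULS) for hybridisation to Agilent bovine arrays. The scanner files deposited for the 36 arrays hold raw intensity per spot, with the local background in its own column, neither background-corrected nor normalized per the file headers. The channel of the longer wavelength was taken as Cy5 and that of the shorter as Cy3; scanner and image software are not stated. The value table deposited by the authors holds 1 ratio per probe and array, taken here as log2 because of the slopes below; base, direction and normalization are not stated. Set against the log2 ratios of the array closest to each column, which was its own in 1 of 36 cases, the values had slopes between 0.95 and 1.25. With the own array their correlations ranged from -0.64 to 1. Because of this, the table was used only for a check.

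The analysis used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Each file held 45220 spots and 14 summary lines, which were left out. Of the spots, 1426 were controls, 153 of them negative controls, and 43794 were probes. Foreground means were corrected with the background medians by normexp with an offset of 50, and log2 ratios were normalized by loess within each array, with control spots at weight 0. No spot of a kept probe was saturated (65535). A spot was above background where its raw signal exceeded the median of the negative controls by 2 scaled median absolute deviations; these thresholds lay between 104.6 and 211.3 in Cy5 and between 133.4 and 247.5 in Cy3. A probe was kept if it was above background in at least 9 of the 18 channels of at least 1 time, which left 33054. Median background intensity lay between 27 and 48 in Cy5 and between 16 and 22 in Cy3, and the percent of probes above background between 44.4 and 84.2 per channel, so that ratios of dim probes are less precise. Where no channel of the lower hour was above background, the fold is given by the mean levels. The lower level is then set at no less than the dimmest probe above background. The SE is not taken off this fold, so it is not a lower limit.

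Gene symbols came from the array annotation, which gave 1 symbol for 21790 probes, several for 0 and none for 22004. They were brought up to date with a RefSeq gene table of assembly ARS-UCD2.0, used for names alone: 20025 were current, 1524 were replaced through a synonym and 241 were kept as given. The annotation names no genome build, so no coordinates are given. A gene was represented by its brightest kept probe.

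Arrays were grouped by the 2 hours on their labels. Each comparison has 3 arrays in each dye orientation, and the labels do not say which belong together, so the 3 arrays of 1 orientation were averaged with those of the other, after turning the sign, in each of the 6 possible arrangements, with the same order in all comparisons. Each arrangement gave 18 averages, which were fitted in limma with 1 coefficient per comparison (12 residual degrees of freedom, empirical Bayes, two-sided). The spread of each probe was thus pooled over all 6 comparisons. These include 44 h vs 68 h and 44 h vs 92 h, whose arrays did not all match their labels. The p was adjusted by Benjamini and Hochberg over the 33054 probes. A probe passed if its adjusted p was under 0.05 in all 6 arrangements, and the adjusted p and the moderated SE given are the largest of the 6. The fit was tested on simulated data in which 20 h vs 44 h held known changes: 61.2, 86.6 and 97 percent of changes of 0.5, 1 and 2 on the log2 scale were called, as were 3 of 32854 unchanged probes, and 0 in the other 5 comparisons.

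The 22 gene lists, written from general knowledge before the data were examined, cover steroidogenesis, cholesterol synthesis, follicular growth and FSH-regulated genes, LH response and ovulation, cell cycle, apoptosis and atresia, the IGF system, basal lamina and extracellular matrix, hypoxia and glycolysis, ER stress, interferon response, cytokines and inflammation, immediate early genes, oxidative stress defence, TGF-beta, BMP and YAP targets, oxidative phosphorylation, ribosomal proteins, and 5 kinds of other cells (theca and stroma, leukocytes, endothelium, erythroid cells, oocyte). The list of TGF-beta, BMP and YAP targets also holds ligands and receptors, such as BMP2, TGFBR3 and BMPR1B, so it does not measure pathway output alone. All lists were tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation. The largest p over the arrangements was adjusted over the lists within a comparison, and members were also counted adjusted over the list alone.

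Genes are named by a rule written before the data were examined. Among probes past the threshold that had 1 symbol and the same sign in all 6 arrays, it takes the 10 genes with the largest rise and the 10 with the largest fall per comparison. It adds up to 4 members of each list past the threshold, those with the smallest adjusted p, or 2 with the largest absolute log2 ratio where none passed. It also adds the landmarks FSHR, LHCGR, CYP19A1, CYP11A1, STAR, INHBA, FST, CCND2, PGR and MKI67, and lets a count of 5 or fewer be named in full. From these the text names a part. The genes named beside the counts shared by 2 intervals and the list member MCM2 were chosen after their values were seen.

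Labels were checked in 2 ways, both set up after the data were seen. Log2 ratios of each array were correlated across probes with those predicted for each of the 12 ordered pairs of hours by a fit to the 24 arrays labelled 20 h vs 44 h, 20 h vs 68 h, 20 h vs 92 h and 68 h vs 92 h, without the array itself. Single channels, made comparable by quantile normalization of the average intensity (Aquantile) and centred per probe within each dye, were correlated with the channels of these 24 arrays, own array left out. These 24 arrays were chosen because all of them matched their labels. For the values through 20 h, the difference of 2 comparisons was fitted to these arrays alone, and the rule of the same sign in 6 arrays was not applied.

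Alternatives to the fit, set before the data were examined, were no background correction, median centring in place of loess, Aquantile after loess, no filter, the 36 arrays unaveraged with a dye intercept, each comparison on its own 3 averages, a network of 3 time coefficients, slide as a random or a fixed block, leave-one-out (an array with its partner), 100 random arrangements, an absolute log2 ratio of at least 1, an estimated correlation, and the mean of all kept probes of a gene. Added after the data were seen were the 24 arrays alone, the values through 20 h with their own alternatives, 1 arrangement with partners chosen by the similarity of their channels, in which the order differs between comparisons, so that it is not among the 6, with leave-one-out in it, further routes in the loops, list medians with slide as a fixed block, and fits to the arrays of 1 slide where it held at least 3 of a comparison (with a dye intercept where it held both orientations). Counts shared by 2 comparisons are set beside the product of their counts over the number of probes. With slide as a fixed block, 20 h vs 44 h, 68 h vs 92 h and 44 h vs 92 h are estimated only through arrays of another comparison on the same slides. The reason is that each of their slides holds 1 orientation of them. The other 3 comparisons then rest on the arrays of 1 slide that holds both their orientations.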

Results

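Gene expression was measured in granulosa cells, the cells that surround the oocyte and line the ovarian follicle and that make oestradiol, taken in vivo by ovum pick-up from Holstein cattle. The labels give 4 times, 20, 44, 68 and 92 h, and do not state the event from which the hours were counted. Each of the 36 arrays carried RNA of 2 times, labelled with Cy3 and Cy5, and 43794 probes. Every pair of times was hybridised directly on 6 arrays, 3 in each dye orientation, so that each time filled 18 channels. The design names 3 biological replicates, and each comparison therefore rested on n = 3 dye-swap averages. The labels do not say which arrays carry the same RNA, and the 6 comparisons share RNA samples, so their results are not independent of each other. The median raw intensity of an array lay between 124.7 and 227.7 in Cy5 and between 162 and 274.2 in Cy3. The percent of probes above the negative control spots averaged 61.3 (SD 7, 18 channels) at 20 h, 69.6 (SD 4.9) at 44 h, 69.7 (SD 6.1) at 68 h and 67.3 (SD 8.2) at 92 h. The number of arrays limited the precision. Of the probes, 33054 were kept, and 17312 of these named 12711 genes. A log2 ratio is that of the later over the earlier hour, its error is the SE, and "rose" or "fell" is written of genes with an adjusted p under 0.05 in all 6 arrangements of dye-swap partners.

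The first question was whether each array held the hours on its label. In 29 of the 36 arrays the labelled pair of hours had the highest correlation across probes among the 12 ordered pairs, and these included all 24 arrays of the comparisons of 20 with 44 h, 20 with 68 h, 20 with 92 h and 68 with 92 h. Of the other 7 arrays, 6 lay on 2 of the 3 slides that carry the arrays labelled 44 h vs 68 h and 44 h vs 92 h. Single channels gave the same split. All 48 channels of the 24 arrays, and the 8 channels of the third of these slides, were nearest to a channel of their labelled hours. Of the 16 channels on the other 2 slides, 6 were nearest to their labelled hours and 16 to the hours that the label of the same area on the other slide gives. These include all 10 channels whose labels differ between the slides. Probes are not independent replicates, so no p is attached to these correlations. No label was changed. The comparisons of 44 h with 68 and 92 h are therefore given as labelled and also through 20 h, from the 24 arrays alone, a route added after the data were seen. For the other 4 comparisons, all of whose arrays matched, the fit on the 24 arrays alone is given where it ended or added the call of a list or of a gene named here, with the members that passed for some of the lists. In the fit to all 36 arrays, the SE and adjusted p of these 4 also draw on the spread of the arrays labelled 44 h vs 68 h and 44 h vs 92 h.

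**Figure D1:**
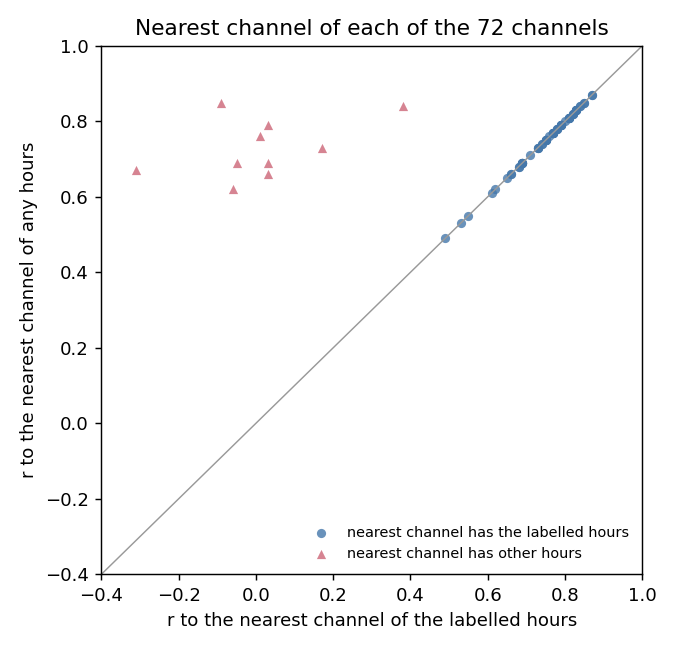
Each point is 1 of the 72 channels. The x axis gives its correlation r across probes with the nearest channel of its labelled hours and the y axis that with the nearest channel of any hours, both taken among the 24 arrays whose comparisons matched their labels (own array left out). The 10 triangles have y values between 0.62 and 0.85 and x values between -0.31 and 0.38; the circles lie on the diagonal, between 0.49 and 0.87.

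Between 20 and 44 h COL3A1, which encodes the chain of type III collagen, rose 48.1-fold (log2 ratio 5.59 ± 1.31, n = 3, adjusted p = 0.021), and FN1, which encodes fibronectin, rose 20.4-fold (log2 ratio 4.35 ± 1.09, n = 3, adjusted p = 0.0265). VNN1, a pantetheinase, rose 27.7-fold (log2 ratio 4.79 ± 0.93, n = 3, adjusted p = 0.00533), and ADAMTS1, a matrix protease induced at ovulation, rose 10.5-fold. STAR, which brings cholesterol to the inner mitochondrial membrane, rose 6.06-fold (log2 ratio 2.60 ± 0.72, n = 3, adjusted p = 0.0382), while CYP11A1, which makes pregnenolone from that cholesterol, fell 2.35-fold (log2 ratio -1.23 ± 0.23, n = 3, adjusted p = 0.00652). Among the largest falls were CENPX (4.64-fold, log2 ratio -2.21 ± 0.42, adjusted p = 0.00426), CENPS (3.57-fold) and RANBP1 (3.73-fold), the first 2 of which encode partners in a complex at kinetochores. Each of these genes had the same sign in 6 of 6 arrays, a condition by which the largest rises and falls were chosen. The 6 arrays hold 3 biological replicates. The log2 ratios of STAR per array, replicates 1 to 6, were 4.55, 2.36, 5.34, 0.48, 2.62 and 0.25. With partners chosen by the similarity of their channels, an arrangement added after the data were seen, the calls of COL3A1 (adjusted p = 0.0743), FN1 (0.0814), ADAMTS1 (0.0605) and STAR (0.0909) ended and those of the other genes of this paragraph did not. In that arrangement the log2 ratio of STAR was 2.66, 1.43 and 3.72 without replicate 2, 3 or 4 and its partner (adjusted p = 0.302, 0.65 and 0.0262), and the call of CYP11A1 ended without replicate 2 or 3 (0.0702 and 0.201).

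Of the 46 measured cell cycle genes, 24 fell and 1 rose between 20 and 44 h (34 and 1 adjusted over the list alone), and the median log2 ratio was -0.79 (adjusted p = 1.89e-16; adjusted p = 0.264 with an estimated correlation). MAD2L1, of the spindle checkpoint, fell 2.93-fold, NCAPG, of condensin, 2.41-fold and RRM1, of ribonucleotide reductase, 2.11-fold. MCM2, of the replicative helicase, was the 1 member that rose (log2 ratio 0.76). Of 38 genes of oxidative phosphorylation, 10 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.35 (adjusted p = 3.91e-09; adjusted p = 0.253 with an estimated correlation); COX7C and UQCRB, subunits of complexes IV and III, fell 2.76-fold and 2.71-fold. Of 20 genes of cholesterol synthesis, 4 fell (5 adjusted over the list alone), among them IDI1 and INSIG1, whose calls ended with the 24 arrays alone (adjusted p = 0.0537 and 0.0687). The median was -0.43 (adjusted p = 4.52e-05; adjusted p = 0.351 with an estimated correlation). In the list of follicular growth and FSH-regulated genes, AMH, the anti-Müllerian hormone, fell 1.94-fold and the other 19 of 20 members did not pass (1 fell adjusted over the list alone); the median was -0.14 (adjusted p = 0.019; adjusted p = 0.352 with an estimated correlation).

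Members of 5 lists of signalling and matrix genes rose over the same interval. Of 17 genes of the TGF-beta, BMP and YAP list, 9 rose (11 adjusted over the list alone), with a median of 0.96 (adjusted p = 6.22e-06; adjusted p = 0.154 with an estimated correlation). CCN2, a matricellular growth factor, rose 7.35-fold, AXL, a receptor tyrosine kinase, 7.25-fold, and BMPR1B, a BMP receptor, 2.80-fold. Of 21 immediate early genes, 6 rose (10 rose and 1 fell adjusted over the list alone), with a median of 1 (adjusted p = 6.22e-06; adjusted p = 0.253 with an estimated correlation), among them KLF4 (8.01-fold) and DUSP1, a MAP kinase phosphatase (4.66-fold). Of 21 interferon response genes, 8 rose (11 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.000113; adjusted p = 0.253 with an estimated correlation), among them IFIT5 (2.49-fold) and ISG15, a ubiquitin-like modifier (2.12-fold). NFKBIA, the inhibitor of NF-kappa-B, rose 6.13-fold as the 1 of 21 cytokine and inflammation genes to pass (3 rose adjusted over the list alone); the median was 1.07 (adjusted p = 0.000164; adjusted p = 0.352 with an estimated correlation). Of 27 genes of basal lamina and extracellular matrix, 4 rose and 1, VCAN, fell (6 and 1 adjusted over the list alone), with a median of 0.53 (adjusted p = 0.00135; adjusted p = 0.352 with an estimated correlation). The call of VCAN ended with the 24 arrays alone (adjusted p = 0.0583), whereas those of COL4A1 (4.73-fold) and SPARC (4.17-fold) did not.

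Of 18 theca and stroma markers, 7 rose between 20 and 44 h (7 adjusted over the list alone), with a median of 0.74 (adjusted p = 0.002; adjusted p = 0.351 with an estimated correlation); DCN, which encodes decorin, rose 12.2-fold and PDGFRA, a receptor of mesenchymal cells, 3.99-fold. The mean log2 ratio of this list per array, replicates 1 to 6, was 2.20, 1.49, 2.63, 0.71, 1.66 and 0.62, and that of the cell cycle list -0.82, -1.11, -0.84, -0.43, -1.25 and -0.33. In the same order it was 1.24, 1.29, 1.39, 0.14, 1.29 and 0.20 for the immediate early list and 1.32, 0.78, 1.57, 0.21, 1.09 and 0.15 for the matrix list. It was 1.20, 1.03, 1.46, 0.04, 1.55 and 0.04 for the endothelial list and -0.55, -0.62, -0.49, 0.10, -0.74 and 0.10 for the follicular growth list. For the cholesterol synthesis list it was -0.86, -0.56, -0.69, 0.00, -0.77 and -0.10, and for the oxidative phosphorylation list -0.55, -0.62, -0.56, -0.12, -0.63 and -0.06. For the interferon response list it was 0.43, 0.49, 0.59, 0.74, 0.72 and 0.69, and for the TGF-beta, BMP and YAP list 1.54, 1.07, 1.77, 0.67, 1.35 and 0.66. For the cytokine list it was 0.98, 1.42, 1.35, 0.48, 1.62 and 0.46, and for the leukocyte list 0.43, 1.01, 0.55, 0.33, 1.45 and 0.32. By the similarity of their channels, replicates 4 and 6 are dye-swap partners. None of 26 leukocyte and none of 14 endothelial markers passed (0 and 4 rose adjusted over the list alone), although the medians of 0.41 and 0.36 passed as lists in limma's set test (adjusted p = 0.00371 and 0.00448; adjusted p = 0.518 and 0.352 with an estimated correlation). CD53, of leukocytes, had a log2 ratio of 2.41 ± 0.84 and KDR, a receptor of endothelial cells, of 3.05 ± 0.91 (adjusted p = 0.099 and 0.052). KDR was not above background in any of the 6 channels of 20 h, so its ratio, 8.31-fold by mean levels, was taken against background. With the 24 arrays alone 2 leukocyte and 6 endothelial markers rose, among them CD53, KDR and ROBO4, a receptor of endothelial cells (adjusted p = 0.0226, 0.0323 and 0.0375). In that fit 29 cell cycle and 2 cholesterol synthesis genes fell, and 8 matrix, 4 cytokine, 6 interferon response, 4 immediate early and 5 theca and stroma genes rose. No member of the 7 erythroid or 15 oocyte markers passed, with medians of 0.04 and 0.00; the oocyte list had a mean of 0.03 and a downward sign in limma's test.

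Apart from the erythroid and oocyte lists, the lists that did not pass between 20 and 44 h held from 1 to 4 genes that did. With the 24 arrays alone the LH response and the apoptosis lists passed upward (adjusted p = 0.0454 and 0.0466; adjusted p = 0.261 and 0.263 with an estimated correlation). Of 12 steroidogenesis genes, STAR rose and CYP11A1 fell (1 rose and 2 fell adjusted over the list alone), with a median of -0.24. In the list of LH response and ovulation 4 of 23 rose, including NRIP1 (1.82-fold) and PLAT, the tissue plasminogen activator (3.09-fold). In that of apoptosis and atresia 4 of 23 rose (6 adjusted over the list alone), including CASP8 (3.93-fold) and CASP9 (1.63-fold), both initiator caspases. IGFBP7 rose 1.84-fold in the IGF system and lost its call with the 24 arrays alone (adjusted p = 0.0673). PFKL and LDHA, enzymes of glycolysis, fell 3.47-fold and 1.93-fold in the hypoxia and glycolysis list. In that of ER stress, PDIA3, MANF and DNAJC3 fell 3.48-fold, 2.12-fold and 1.33-fold, and all 3 lost their calls with the 24 arrays alone (adjusted p = 0.0536, 0.0658 and 0.0782). SRXN1 rose 3.41-fold and PRDX4 fell 1.73-fold among genes of oxidative stress defence, and RPL15 rose 1.68-fold among 31 ribosomal protein genes.

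In all, 780 probes rose and 978 fell between 20 and 44 h, of which 288 and 279 changed at least 2-fold, and they covered 453 genes that rose and 484 that fell. With the 24 arrays alone 1091 probes rose and 977 fell, in 626 and 477 genes, and 1446 of these 2068 passed in both fits. The count was 0 in limma with the comparison's own 3 averages only (5124 at an unadjusted p under 0.05 in the fit that pools the spread), and 250 with slide as a fixed block; 338, 203 and 662 passed without replicate 2, 3 or 4 and its partner. With partners chosen by the similarity of their channels, 962 passed (416 up and 546 down), 925 of them among these 1758, and 153, 64 and 1369 passed without replicate 2, 3 or 4 and its partner in that arrangement. All 12 lists that passed did so there too, as did the LH response and apoptosis lists (adjusted p = 0.0379 and 0.0347), and with an estimated correlation the TGF-beta, BMP and YAP list alone passed in this comparison (adjusted p = 0.028). Of the 84 named genes of the comparison 35 lost their calls. Among those in the text above, beside the 4 given, they were DCN (adjusted p = 0.0555), INSIG1 (0.115), IDI1 (0.129), AMH (0.0725), PLAT (0.0941), CASP8 (0.0771), IGFBP7 (0.0925), SPARC (0.0582), PFKL (0.0603), LDHA (0.0885), MANF (0.0651), NFKBIA (0.0714), KLF4 (0.0515), SRXN1 (0.0791), PRDX4 (0.0515), CCN2 (0.0619), AXL (0.0503) and PDGFRA (0.0543). With slide as a fixed block the medians of the cell cycle, TGF-beta, BMP and YAP, and theca and stroma lists were -0.46, 0.46 and 0.30, those of the cholesterol synthesis and oxidative phosphorylation lists -0.11 and -0.01, that of the interferon response list 0.17 and that of the leukocyte list 0.82. The median of the follicular growth list turned to 0.18. In this fit 20 h vs 44 h is estimated only through the arrays of 20 h vs 68 h on the same slides, so the turn does not show an effect of slide. Each of 2 slides held 3 arrays of a single dye orientation, so that hours and dyes cannot be told apart within 1 slide. There 0 probes passed in limma where 44 h was in Cy5 (6086 at an unadjusted p under 0.05) and 1024 where it was in Cy3 (730 up and 294 down). These fits were added after the data were seen. Their cell cycle medians were -0.79 and -0.84. Those of the follicular growth list were -0.05 and -0.38.

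Between 20 and 68 h the rises were led by VNN1, at 80.2-fold (log2 ratio 6.33 ± 0.93, n = 3, adjusted p = 0.000419). MXRA8, a matrix remodelling protein, rose 19.4-fold (log2 ratio 4.28 ± 0.74, n = 3, adjusted p = 0.00104), PDK4, a kinase that blocks pyruvate dehydrogenase, 17.3-fold, and NRP1, a co-receptor for semaphorins and VEGF, 13.1-fold. ANGPT2, an angiopoietin, rose 8.26-fold (log2 ratio 3.05 ± 0.53, n = 3, adjusted p = 0.00115). MYH11, the myosin of smooth muscle, rose 11.2-fold and NDP, a ligand of Frizzled receptors, 9.48-fold by their mean levels. Neither was above background in any of the 6 channels of 20 h in this comparison. Among the largest falls were GPR85 (10.5-fold, log2 ratio -3.39 ± 0.85, n = 3, adjusted p = 0.00935), CCNB1, which encodes cyclin B1 (6.62-fold, log2 ratio -2.73 ± 0.47, n = 3, adjusted p = 0.00101), and KIF11 and NUF2, of the mitotic spindle and kinetochore (6.04-fold and 5.67-fold). STAR had a log2 ratio of 0.03 ± 0.72 and did not pass (adjusted p = 0.984).

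Of the 46 cell cycle genes, 37 fell and 1 rose between 20 and 68 h (38 and 1 adjusted over the list alone), with a median of -1.25 (adjusted p = 3.97e-16; adjusted p = 0.457 with an estimated correlation). PCNA, the sliding clamp of replication, fell 3.41-fold and TYMS, which makes thymidylate, 2.82-fold. Of 31 ribosomal protein genes, 18 rose and 2 fell (21 and 2 adjusted over the list alone), with a median of 0.74 (adjusted p = 4.17e-05; adjusted p = 0.527 with an estimated correlation); RPL18 rose 3.27-fold and RPS15 3.02-fold. Of 21 immediate early genes, 11 rose (14 adjusted over the list alone), with a median of 1.15 (adjusted p = 2.79e-05; adjusted p = 0.457 with an estimated correlation), including IER3 (5.09-fold), DUSP1 (3.80-fold) and EGR1, a zinc finger transcription factor (2.89-fold). Of 21 interferon response genes, 10 rose (12 adjusted over the list alone), with a median of 0.33 (adjusted p = 0.000998; adjusted p = 0.457 with an estimated correlation), including ISG15 (4.07-fold) and IFIT5 (2.54-fold). Of 17 genes of the TGF-beta, BMP and YAP list, 6 rose (6 adjusted over the list alone), with a median of 0.63 (adjusted p = 0.0206; adjusted p = 0.504 with an estimated correlation), including TGFBR3, the betaglycan co-receptor (5.69-fold), and BMPR1B (4.78-fold). Of 20 cholesterol synthesis genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.52 (adjusted p = 0.00286; adjusted p = 0.527 with an estimated correlation), including IDI1 (3.30-fold) and INSIG1 (2.79-fold). Of 38 oxidative phosphorylation genes, 14 fell and 1 rose (14 and 2 adjusted over the list alone), with a median of -0.15 (adjusted p = 0.0327; adjusted p = 0.612 with an estimated correlation), including UQCRB (3.55-fold).

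The other 15 lists did not pass between 20 and 68 h. Members of the apoptosis and atresia list went both ways, with 9 of 23 up, among them GADD45A, a stress sensor (8.22-fold), and CLU, which encodes clusterin (3.56-fold), and 2 down, among them CYCS, which encodes cytochrome c (4.17-fold). The ER stress list was as mixed, with 4 of 20 up, led by ASNS, which makes asparagine (8.01-fold), and 6 down, including DNAJB11 (2.10-fold) and DNAJC3 (1.75-fold). In the matrix list 6 of 27 rose and 3 fell; LAMB1, a laminin chain, rose 8.25-fold and HSPG2, which encodes perlecan, fell 1.93-fold. Of the hypoxia and glycolysis list 4 of 28 rose and 3 fell, and of the oxidative stress list 3 of 24 rose and 5 fell. The hypoxia and glycolysis list had a median of 0.04 and a mean of 0.07 and a downward sign in limma's test (adjusted p = 0.983), and the endothelial list a median of 0.00, a mean of 0.19 and a downward sign. PGR, the progesterone receptor, fell 2.17-fold in the LH response list, and GJA1, which encodes connexin 43, 1.71-fold in the follicular growth list. CYP11A1 fell 1.67-fold. The last 2 calls ended with the 24 arrays alone (adjusted p = 0.0606 and 0.0611). No member of the IGF list passed, IL18 rose 6.26-fold and CCL5 1.39-fold in the cytokine list, and of the other-cell lists only theca and stroma (4 of 18, including MYH11 and ACTA2) and erythroid (SLC4A1, 1.13-fold, adjusted p = 0.0518 with the 24 arrays alone) had members that passed. DCN rose 5.39-fold and lost its call with the 24 arrays alone (adjusted p = 0.055).

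In all, 3569 probes rose and 2724 fell between 20 and 68 h, with 891 and 663 of them at least 2-fold, in 1764 genes that rose and 1229 that fell. With the comparison's own 3 averages 1930 passed, of which 1704 were among these 6293, and 9683 passed with slide as a random block. Without replicate 1, 3 or 5 and its partner 3324, 2804 and 2411 passed. With slide as a fixed block the medians of the cholesterol synthesis and oxidative phosphorylation lists were -0.28 and -0.03. With median centring the oxidative phosphorylation list no longer passed (adjusted p = 0.282). With partners chosen by similarity 6131 probes passed, and of the genes tested there GJA1, DCN and PDGFRA lost their calls (adjusted p = 0.104, 0.0865 and 0.0653). Without replicate 1, 3 or 5 and its partner in that arrangement 4343, 3119 and 1527 passed.

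Between 20 and 92 h CYP19A1, the aromatase that makes oestradiol, fell 14.9-fold (log2 ratio -3.89 ± 0.80, n = 3, adjusted p = 0.00183), INHBA, the beta A subunit of inhibin and activin, 5.73-fold (log2 ratio -2.52 ± 0.42, n = 3, adjusted p = 0.000399), FST, which encodes the activin-binding follistatin, 7.81-fold, and CCND2, which encodes cyclin D2, 4.78-fold. The log2 ratios of CYP19A1 per array, replicates 1 to 6, were -5.12, -5.38, -1.90, -1.92, -4.42 and -4.61. With partners chosen by similarity it was -3.21, -4.88 and -3.58 without replicate 1, 3 or 5 and its partner (adjusted p = 0.0807, 0.0124 and 0.0592). PGR fell 6.49-fold (log2 ratio -2.70 ± 0.30, n = 3, adjusted p = 2.59e-05). STAR rose 16.8-fold (log2 ratio 4.07 ± 0.72, n = 3, adjusted p = 0.000714). Among the largest changes were rises of VNN1 (55.6-fold, log2 ratio 5.80 ± 0.93), ANKRD1, a target of YAP (41.7-fold, 5.38 ± 0.66), and KRT8, which encodes keratin 8 (39.0-fold), and falls of LRP8, a receptor of apolipoprotein E (25.8-fold, -4.69 ± 0.70), CCNB1 (18.4-fold) and HMGCS1, which makes HMG-CoA for cholesterol synthesis (18-fold). Each of these genes had the same sign in 6 of 6 arrays, a condition by which the largest changes were chosen. The receptors FSHR and LHCGR had log2 ratios of -0.26 ± 0.26 and -0.10 ± 0.13 and did not pass, and LHCGR was above background in 1 of 6 channels of 20 h and in 0 of 6 of 92 h.

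**Figure D2:**
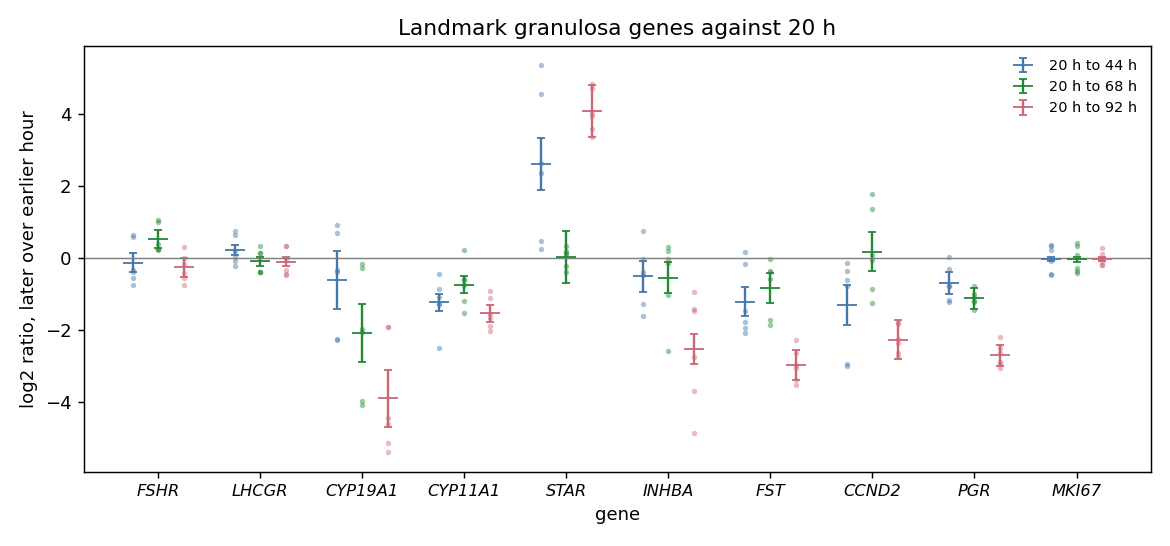
Log2 ratios of 10 landmark genes of granulosa cells at 44, 68 and 92 h over 20 h. Points are the 6 arrays of a comparison, dashes the means and bars the SE. The SE pools a probe's spread over all 6 comparisons, so the bars do not show that of the points. CYP19A1 had means of -0.60, -2.08 and -3.89 (only the last passed) and STAR of 2.60, 0.03 and 4.07. The means of MKI67, a marker of cycling cells, lay between -0.04 and -0.02. At 68 h over 20 h its arrays gave -0.27, -0.41 and -0.37 with 68 h in Cy5 and 0.42, 0.33 and 0.08 with 68 h in Cy3. The sign followed the dye, so these means do not show that MKI67 was unchanged.

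Of the 46 cell cycle genes, 42 fell and 1, MCM2, rose between 20 and 92 h (42 and 1 adjusted over the list alone), with a median of -1.75 (adjusted p = 7.19e-22; adjusted p = 0.168 with an estimated correlation). BIRC5, which encodes survivin, fell 9.11-fold and BUB1B, of the spindle checkpoint, 9.39-fold. Of 20 cholesterol synthesis genes, 17 fell (17 adjusted over the list alone), with a median of -1.41 (adjusted p = 7.5e-10; adjusted p = 0.168 with an estimated correlation), including SQLE, which makes squalene epoxide (7.25-fold), and FDPS (4.23-fold). Of 20 follicular growth and FSH-regulated genes, 11 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.58 (adjusted p = 0.000116; adjusted p = 0.169 with an estimated correlation). Of 12 steroidogenesis genes, 6 fell and STAR rose (6 and 2 adjusted over the list alone), with a median of -0.44 (adjusted p = 0.0181; adjusted p = 0.168 with an estimated correlation); CYP11A1 fell 2.88-fold and HSD17B1, which makes oestradiol from oestrone, 1.79-fold. Of 38 oxidative phosphorylation genes, 19 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -0.50 (adjusted p = 1.49e-05; adjusted p = 0.212 with an estimated correlation), including UQCRB (4.31-fold). Of 28 hypoxia and glycolysis genes, 12 fell and 4 rose (15 and 4 adjusted over the list alone), with a median of -0.51 (adjusted p = 0.00563; adjusted p = 0.254 with an estimated correlation). PFKL fell 5.21-fold and LDHA 3.94-fold, whereas MXI1, a MYC antagonist, rose 4.13-fold.

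Of 17 genes of the TGF-beta, BMP and YAP list, 12 rose (12 adjusted over the list alone) between 20 and 92 h, with a median of 1.63 (adjusted p = 3.05e-05; adjusted p = 0.168 with an estimated correlation), including BMPR1B (5.08-fold) and ID2, a target of BMP signalling (4.35-fold). Of 21 immediate early genes, 12 rose (13 adjusted over the list alone), with a median of 1.04 (adjusted p = 1.49e-05; adjusted p = 0.169 with an estimated correlation); MYC rose 12.1-fold and NR4A1, an orphan nuclear receptor, 4.67-fold. Of 21 interferon response genes, 13 rose (13 adjusted over the list alone), with a median of 0.58 (adjusted p = 0.000116; adjusted p = 0.168 with an estimated correlation). IFIT5 rose 5.78-fold and ISG15 3.98-fold. IRF9, not above background in any channel of 20 h in this comparison, rose 1.43-fold by its mean levels. Of 21 cytokine and inflammation genes, 5 rose (5 adjusted over the list alone), with a median of 1.06 (adjusted p = 0.0167; adjusted p = 0.639 with an estimated correlation), including IL18 (13.1-fold) and IL6 (2.43-fold); 9 rose with the 24 arrays alone (10 adjusted over the list alone). Of 23 apoptosis and atresia genes, 12 rose and 3 fell (13 and 4 adjusted over the list alone), with a median of 0.41 (adjusted p = 0.0127; adjusted p = 0.254 with an estimated correlation); TP53INP1, a target of p53, rose 7.92-fold and CLU 7.75-fold. Of 27 matrix genes, 11 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 0.34 (adjusted p = 0.0387; adjusted p = 0.591 with an estimated correlation); LAMB1 rose 9.94-fold, COL4A5 8.24-fold and TIMP1, an inhibitor of matrix proteases, 6.33-fold, while VCAN fell 6.77-fold. Of 31 ribosomal protein genes, 13 rose and 3 fell (14 and 3 adjusted over the list alone), with a median of 0.38 (adjusted p = 0.0288; adjusted p = 0.652 with an estimated correlation).

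Of 26 leukocyte markers 5 rose between 20 and 92 h (3 adjusted over the list alone), with a median of 0.37 (adjusted p = 0.0395; adjusted p = 0.678 with an estimated correlation). C1QB and CD68, of macrophages, rose 2.91-fold and 2.87-fold. CD163 and C1QC, not above background in any of the 6 channels of 20 h in this comparison, rose 2.75-fold and 1.27-fold by their mean levels. With the 24 arrays alone 11 leukocyte markers rose (12 adjusted over the list alone). The theca and stroma list did not pass, with 6 of 18 up and 2 down (7 and 2 adjusted over the list alone); MYH11, above background in 1 of 6 channels of 20 h here, rose 17.7-fold and PDGFRA 7.98-fold. No endothelial marker passed, and the median of that list was 0.00 with a mean of 0.26; SELP, which encodes P-selectin, rose with the 24 arrays alone (log2 ratio 1.92, adjusted p = 0.0306). SLC4A1, of erythroid cells, rose 1.14-fold, and the oocyte markers KPNA7 and H1-8 fell 1.57-fold and 1.15-fold (0 fell adjusted over the list alone). Of the lists that did not pass, the LH response list had 5 of 23 up and 2 down, including PTX3, of the cumulus matrix (4.39-fold up), the IGF list 4 of 14 up and 1 down, including STC1 (8.48-fold up), the ER stress list 4 of 20 up and 7 down, including XBP1 (1.81-fold down), and the oxidative stress list 6 of 24 up and 9 down, including PRDX2 (2.75-fold up) and CAT, which encodes catalase (2-fold down). In all, 4614 probes rose and 4146 fell, with 1466 and 1010 of them at least 2-fold, in 2295 genes that rose and 1697 that fell. Without replicate 1, 3 or 5 and its partner 5249, 5138 and 5643 passed. With partners chosen by similarity 8798 passed, and 5689, 5435 and 6018 without replicate 1, 3 or 5 and its partner. The call of CD163 ended there (adjusted p = 0.0686), and the ER stress list passed downward (adjusted p = 0.0429). The leukocyte list no longer passed with no background correction, median centring or no filter (adjusted p = 0.0638, 0.188 and 0.0723), nor did the steroidogenesis and matrix lists with median centring (adjusted p = 0.0582 and 0.0778).

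Between 68 and 92 h STAR rose 17.4-fold (log2 ratio 4.12 ± 0.72, n = 3, adjusted p = 0.00304). INHBB, the beta B subunit of inhibin and activin, fell 7.39-fold (log2 ratio -2.89 ± 0.55, n = 3, adjusted p = 0.0043), INHBA 4.75-fold (log2 ratio -2.25 ± 0.42, n = 3, adjusted p = 0.00325), FST 4.41-fold, CCND2 5.2-fold, PGR 3.08-fold and AMH 3.05-fold. FSHR, the FSH receptor, fell 1.78-fold (log2 ratio -0.83 ± 0.26, n = 3, adjusted p = 0.0471). CYP19A1 did not pass (log2 ratio -1.75 ± 0.80, arrays -2.45 to -1.23, adjusted p = 0.153). This SE pools all 6 comparisons. ANKRD1 rose 30.2-fold (log2 ratio 4.92 ± 0.66, n = 3, adjusted p = 0.00089) and SPP1 (osteopontin) 17.5-fold. KRT8 and KRT18, partner keratins, rose 8.85-fold and 8.05-fold. IHH, a hedgehog ligand, fell 5.87-fold and SCD, which makes monounsaturated fatty acids, 5.28-fold.

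Of 20 cholesterol synthesis genes, 14 fell between 68 and 92 h (16 adjusted over the list alone), with a median of -0.90 (adjusted p = 1.48e-08; adjusted p = 0.326 with an estimated correlation), including HMGCS1 (5.22-fold) and FDFT1, which makes squalene (3.20-fold). Of 46 cell cycle genes, 20 fell (25 adjusted over the list alone), with a median of -0.71 (adjusted p = 1.16e-08; adjusted p = 0.39 with an estimated correlation), including NUSAP1 (3.29-fold) and AURKB, a mitotic kinase (2.57-fold). Of 20 follicular growth and FSH-regulated genes, 10 fell (10 adjusted over the list alone), with a median of -0.54 (adjusted p = 0.000335; adjusted p = 0.326 with an estimated correlation). Of 28 hypoxia and glycolysis genes, 11 fell (12 adjusted over the list alone), with a median of -0.51 (adjusted p = 0.000695; adjusted p = 0.326 with an estimated correlation), including LDHA (2.50-fold) and CA9, a carbonic anhydrase (2.33-fold). Of 38 oxidative phosphorylation genes, 3 fell (2 adjusted over the list alone), with a median of -0.31 (adjusted p = 9e-05; adjusted p = 0.36 with an estimated correlation): NDUFV1 (1.63-fold), NDUFV2 (1.60-fold) and NDUFS3 (1.41-fold, adjusted p = 0.08 with the 24 arrays alone). Of 17 genes of the TGF-beta, BMP and YAP list, 5 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.57 (adjusted p = 0.00176; adjusted p = 0.326 with an estimated correlation), including AXL (10.2-fold) and ID2 (3.61-fold). Of 21 cytokine genes, CCL2, which attracts monocytes, and IL6 rose 6.43-fold and 2.69-fold (2 adjusted over the list alone), with a median of 0.67 (adjusted p = 0.0427; adjusted p = 0.756 with an estimated correlation).

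The other lists did not pass between 68 and 92 h. With the 24 arrays alone the leukocyte and apoptosis lists passed upward (adjusted p = 0.0047 and 0.0162; adjusted p = 0.566 and 0.248 with an estimated correlation). In that fit 6 of 26 leukocyte markers, 4 of 23 apoptosis and 5 of 21 cytokine genes rose, and 11 cholesterol synthesis and 25 cell cycle genes fell. Of 12 steroidogenesis genes STAR rose and 4 fell (1 and 5 adjusted over the list alone), with CYP11A1 at 1.82-fold down (adjusted p = 0.0543 with the 24 arrays alone) and NR5A2, a nuclear receptor of granulosa cells, at 1.89-fold down. The LH response list had 3 of 23 up and 3 down, with PTX3 at 5.94-fold up; its median and mean were 0.05 and 0.17 and limma's test had a downward sign (adjusted p = 0.967). STC1 and IGF2R rose 6.65-fold and 2.26-fold in the IGF list, TP53INP1 3.10-fold in the apoptosis list, and TIMP1 4.13-fold and THBS1, which encodes thrombospondin 1, 6.48-fold in the matrix list (THBS1, adjusted p = 0.0529 with the 24 arrays alone). FOSL1, an AP-1 subunit, rose 3.81-fold and IFIT5 2.42-fold. Of the markers of other cells, CNN1 and LUM, of smooth muscle and stroma, rose 5.75-fold and 5.09-fold and C1QB and CD68 2.46-fold and 2.01-fold, while KPNA7 fell 1.96-fold. No ER stress, ribosomal protein, endothelial or erythroid gene passed, although with the 24 arrays alone 3 ribosomal protein genes, RPL8, RPS19 and RPL13, fell (log2 ratio -1.05, -0.97 and -0.50, adjusted p = 0.0418, 0.00797 and 0.034) and CLDN5, of endothelial tight junctions, rose (0.35, 0.0253). Here the erythroid list had a median of 0.05, a mean of -0.11 and an upward sign in limma's test. GCLC, of glutathione synthesis, fell 1.32-fold (adjusted p = 0.0613 with the 24 arrays alone).

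In all, 1452 probes rose and 1780 fell between 68 and 92 h, with 264 and 320 of them at least 2-fold, in 652 genes that rose and 802 that fell. In limma the count was 0 with the comparison's own 3 averages only (7661 at an unadjusted p under 0.05 in the fit that pools the spread) and 294 with slide as a fixed block. Without replicate 4, 5 or 6 and its partner 832, 5.3e+02 and 1223 passed. With partners chosen by similarity 2754 passed, and 815, 365 and 1933 without replicate 4, 5 or 6 and its partner. Of the genes named above KRT8 (adjusted p = 0.0531), CCL2 (0.0538), GCLC (0.0633), NDUFS3 (0.0822), CD68 (0.115), C1QB (0.0929) and FSHR (0.0556) lost their calls there, and the apoptosis and leukocyte lists passed (adjusted p = 0.0331 and 0.0415). The cytokine list no longer passed with no filter (adjusted p = 0.0804). With slide as a fixed block the medians of the cholesterol synthesis, cell cycle and TGF-beta, BMP and YAP lists were -0.95, -0.71 and 0.54, and those of the follicular growth and cytokine lists were -0.81 and 0.01. Each of 2 slides again held 3 arrays of a single dye orientation. Within 1 slide 3063 probes passed where 92 h was in Cy5 (1429 up and 1634 down) and 1928 where it was in Cy3 (717 up and 1211 down). The medians of the cholesterol synthesis list were -1.14 and -0.88 and those of the cytokine list 0.67 and 0.52.

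**Figure D3:**
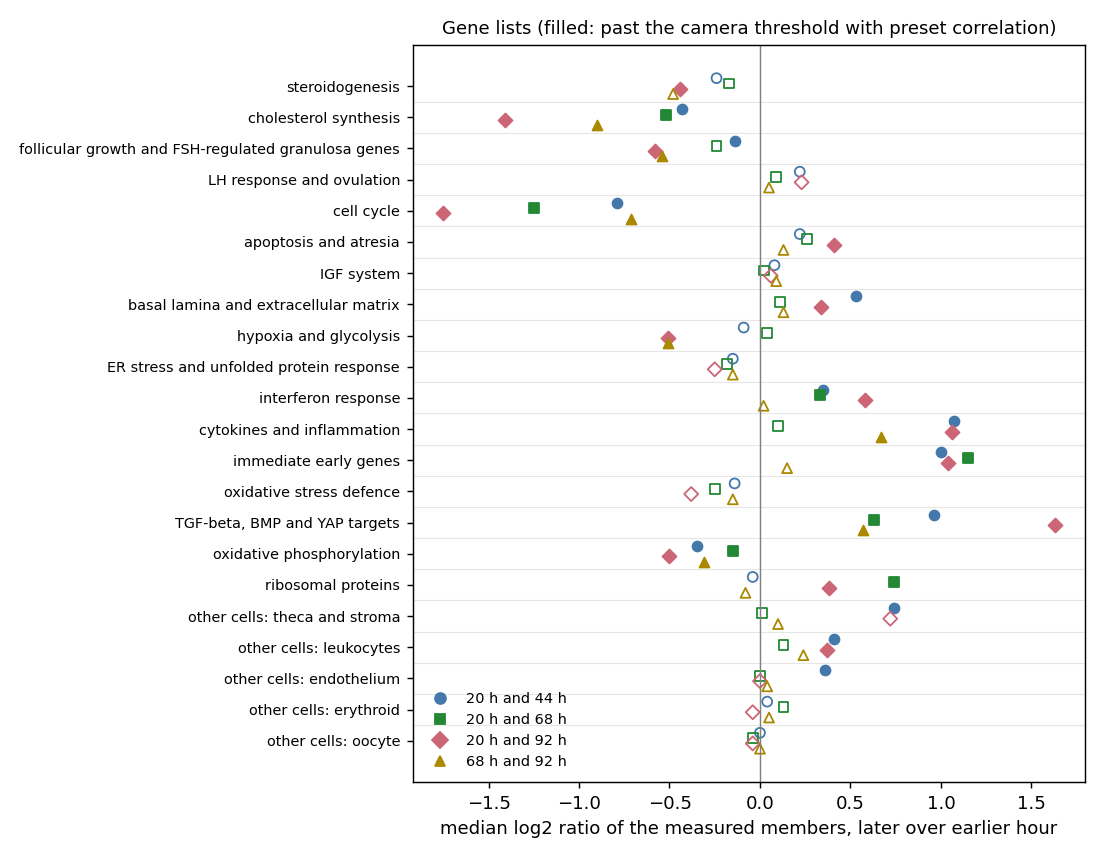
Median log2 ratio of the measured members of each of the 22 gene lists in 4 comparisons, later over earlier hour. Filled symbols passed limma's set test with a preset correlation, and 0 passed with an estimated correlation in these fits. The cell cycle medians were -0.79, -1.25, -1.75 and -0.71 and the cholesterol synthesis medians -0.43, -0.52, -1.41 and -0.90 at 44, 68 and 92 h over 20 h and at 92 h over 68 h.

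Between 44 and 68 h, on the arrays as labelled, 0 probes passed in limma and 2184 had an unadjusted p under 0.05. FN1 had a log2 ratio of -3.93 ± 1.09, COL3A1 of -3.53 ± 1.31 and STAR of -2.77 ± 0.72, and none passed (adjusted p = 0.401 for each). Of the 22 lists 5 passed upward and 6 downward although no member passed. These were cholesterol synthesis (median 0.30, adjusted p = 5.1e-05), follicular growth (0.23, 0.000223), cell cycle (0.16, 0.0064), oxidative phosphorylation (0.18, 5.09e-06) and ribosomal proteins (0.04, 0.0351) upward, and matrix (-0.44, 0.000126), cytokines (-0.69, 5.51e-05), TGF-beta, BMP and YAP targets (-0.31, 0.0064), stroma (-0.61, 0.000219), leukocytes (-0.52, 0.000126) and endothelium (-0.50, 0.000126) downward. With an estimated correlation their adjusted p lay between 0.372 and 0.574. Among these 11 lists only the endothelial one had members that passed adjusted over the list alone, 6 that fell. The mean log2 ratio per array, replicates 1 to 6, was -0.18, -0.17, -0.02, 0.65, -0.89 and 1.5 for the cell cycle list, 0.38, 0.06, 0.05, 0.97, -0.94 and 1.31 for the cholesterol synthesis list and 0.48, -0.05, -0.02, 0.86, -0.56 and 1.36 for the follicular growth list. Replicates 4, 5 and 6 are those of this comparison whose labelled pair of hours did not have the highest correlation. The steroidogenesis list did not pass and had a median of 0.15, a mean of -0.03 and an upward sign in limma's test (1 fell adjusted over the list alone). With slide as a fixed block the medians of the cell cycle, endothelial and leukocyte lists were 0.31, -0.25 and -0.22. That of the ribosomal protein list turned to -0.04. These equal the medians of the 4 arrays of this comparison on 1 slide, with both orientations. That slide is 1 of the 2 whose channels were nearest to the hours on each other's labels, so this is no separate check. With the mean of all kept probes that list no longer passed (adjusted p = 0.0833). The hypoxia and glycolysis list passed upward with partners chosen by similarity (adjusted p = 0.0492).

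Taken through 20 h, from the 24 arrays whose comparisons matched their labels, 398 probes rose and 364 fell between 44 and 68 h, in 213 and 193 genes. MYH11 rose 6.18-fold (log2 ratio 2.63 ± 0.52, adjusted p = 0.0299), KRT2, a keratin, 4.21-fold, IHH 3.75-fold (log2 ratio 1.91 ± 0.40, adjusted p = 0.0379), ANGPT2 3.56-fold and SOX4, a transcription factor, 3.21-fold. GCH1, which starts tetrahydrobiopterin synthesis, fell 3.80-fold (log2 ratio -1.93 ± 0.40, adjusted p = 0.0311), SPRY2, an inhibitor of receptor tyrosine kinase signalling, 3.36-fold and FDX1, which passes electrons to CYP11A1, 1.84-fold. STAR had a log2 ratio of -2.57 ± 0.87 and did not pass (adjusted p = 0.148). Each value is a difference of 2 comparisons of 3 averages, and the condition of the same sign in 6 arrays was not applied. Of 31 ribosomal protein genes, 7 rose (17 adjusted over the list alone), with a median of 0.70 (adjusted p = 2.52e-10; adjusted p = 0.491 with an estimated correlation), including RPS19 (3.06-fold) and RPL32 (2.13-fold). KIF23, of the central spindle, fell 1.45-fold as the 1 of 46 cell cycle genes that passed (2 fell adjusted over the list alone); the median was -0.25 (adjusted p = 0.000256; adjusted p = 0.89 with an estimated correlation), opposite in sign to the 0.16 of the arrays as labelled. The cytokine, leukocyte and endothelial lists passed with medians of -0.51, -0.27 and -0.38 and no member (adjusted p = 0.0198, 0.0198 and 0.00296; adjusted p = 0.89 for each with an estimated correlation). Of the 11 lists that passed as labelled, 6 did not pass through 20 h: cholesterol synthesis (median -0.03, adjusted p = 0.978), follicular growth (0.05, 0.978), oxidative phosphorylation (0.12, 0.297), matrix (-0.22, 0.0605), TGF-beta, BMP and YAP targets (-0.32, 0.665) and stroma (-0.49, 0.0605). The count of 762 was 146 with median centring in place of loess (103 up and 43 down), and 52, 46, 157 and 59 without replicate 2 or 3 of 20 h vs 44 h or replicate 3 or 5 of 20 h vs 68 h. Without replicate 4 of 20 h vs 44 h it was 833 (336 up and 497 down).

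Between 44 and 92 h, on the arrays as labelled, 0 probes passed in limma and 1180 had an unadjusted p under 0.05. ANKRD1 had a log2 ratio of 2.44 ± 0.66, INHBB of -1.71 ± 0.55 and HMGCS1 of -1.56 ± 0.59, and none passed (adjusted p = 0.73 for each). Of the 22 lists 7 passed with no member past the threshold. The medians were -0.50 for cholesterol synthesis (adjusted p = 1.68e-10; 8 fell adjusted over the list alone), -0.24 for follicular growth (3.41e-06), -0.41 for cell cycle (8.59e-15), -0.18 for hypoxia and glycolysis (0.0359), -0.14 for oxidative phosphorylation (0.000813), 0.16 for apoptosis (0.0118) and 0.39 for TGF-beta, BMP and YAP targets (0.00503; 1 rose adjusted over the list alone). With an estimated correlation their adjusted p lay between 0.323 and 0.461. The theca and stroma list did not pass and had a median of -0.01, a mean of -0.02 and an upward sign in limma's test. With slide as a fixed block the medians of the cell cycle, follicular growth and TGF-beta, BMP and YAP lists were -0.06, -0.12 and 0.74. Those of the matrix and stroma lists, which did not pass, were 0.71 and 0.87. With median centring the oxidative phosphorylation list no longer passed (adjusted p = 0.21). Within 1 slide 1443 probes passed where 92 h was in Cy5 (871 up and 572 down) and 0 in limma where it was in Cy3 (3195 at an unadjusted p under 0.05), with cell cycle medians of -0.98 and 0.06. The latter slide is 1 of the 2 whose channels were nearest to the hours on each other's labels.

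Taken through 20 h, 576 probes rose and 421 fell between 44 and 92 h, in 309 and 195 genes. APOD, a lipocalin, rose 23.6-fold (log2 ratio 4.56 ± 0.52, adjusted p = 0.00416), ANKRD1 15.4-fold (log2 ratio 3.95 ± 0.63, adjusted p = 0.00886) and GATM, of creatine synthesis, 8.96-fold. LRP8 fell 16.5-fold (log2 ratio -4.05 ± 0.65, adjusted p = 0.0126), MSMO1 and CYP51A1, of cholesterol synthesis, 7.41-fold and 6.59-fold, INHBA 4.04-fold and PGR 4.00-fold. Of 46 cell cycle genes, 20 fell (32 adjusted over the list alone), with a median of -0.93 (adjusted p = 1.62e-18; adjusted p = 0.33 with an estimated correlation), including CCNB1 (6.09-fold). Of 20 cholesterol synthesis genes, 5 fell (13 adjusted over the list alone), with a median of -1.04 (adjusted p = 1.3e-08; adjusted p = 0.374 with an estimated correlation). INHBA and INHBB were the 2 of 20 follicular growth genes that fell (4 adjusted over the list alone), with a median of -0.42 (adjusted p = 0.00213; adjusted p = 0.374 with an estimated correlation). RPL30 and RPL5 were the 2 of 31 ribosomal protein genes that rose (6 adjusted over the list alone), with a median of 0.55 (adjusted p = 1.32e-05; adjusted p = 0.374 with an estimated correlation). The endothelial list passed with a median of -0.38 and no member (adjusted p = 0.00606; adjusted p = 0.477 with an estimated correlation). Of the 7 lists that passed as labelled, 4 did not pass through 20 h: hypoxia and glycolysis (median -0.27, adjusted p = 0.0558), oxidative phosphorylation (-0.12, 0.282), apoptosis (0.09, 0.0584) and TGF-beta, BMP and YAP targets (0.48, 0.0584). The count of 997 was 599 with median centring (475 up and 124 down), and 258, 370, 377, 305 and 274 without replicate 2 or 3 of 20 h vs 44 h or replicate 1, 3 or 5 of 20 h vs 92 h.

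The 6 comparisons close loops, so that a direct ratio can be set against a sum of others. Across the 33054 probes the direct ratio of 92 over 20 h correlated with the sum of 20 to 68 h and 68 to 92 h at r = 0.98 with a slope of 0.97, a route added after the data were seen. The routes through arrays labelled 44 h vs 68 h gave r = 0.85 and a slope of 1.07 for 20 to 92 h, r = 0.79 and 1.3 for 20 to 68 h, and r = 0.65 and 0.41 for 44 to 92 h. Against the route through 20 h, the arrays labelled 44 h vs 68 h had r = 0.61 and a slope of 0.46 and those labelled 44 h vs 92 h r = 0.87 and 0.44.

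Genes that rose or fell in the first interval moved the same way in the last one more often than independence would give. Of the 780 probes that rose between 20 and 44 h and the 1452 that rose between 68 and 92 h, 146 were shared (34.3 under independence), among them those of STAR, KRT8 and AXL. Of the 978 and 1780 that fell, 208 were shared (52.7 under independence), among them those of CYP11A1, AMH and BIRC5. The calls of STAR, KRT8, AXL and AMH between 20 and 44 h ended with partners chosen by similarity. Only 11 rose and then fell (42 under independence) and 14 fell and then rose (43 under independence). The log2 ratios of the 2 intervals, which share no time, correlated across probes at r = 0.41, and with median centring 88 and 115 probes were shared. With arrays labelled 44 h vs 92 h or 44 h vs 68 h in the other 2 pairs of comparisons, 0 probes were shared, since 0 had passed in limma; r was 0.48 for 20 to 68 h against 44 to 92 h and -0.40 for 44 to 68 h against 20 to 92 h.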

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

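Among the tests in this part, those of the label pattern and of the markers of other cells were chosen only after the result was seen, whereas the search for single arrays far from the other 5 was set before the data were examined. It divided the gap between the highest or lowest array and its neighbour by the range of the 6 arrays, for 622 values over the 6 comparisons together, against Dixon's critical value for 6 arrays. Chance alone puts about 1 in 20 groups past that value, or 31 of 622, if the 6 arrays are independent. The design names 3 biological replicates for the 6 arrays, so a replicate that stands apart in 2 arrays is missed. The value was passed by 17, 10 of them in 44 h vs 68 h, 3 in 68 h vs 92 h, 2 in 20 h vs 68 h, 2 in 44 h vs 92 h and 0 in 20 h vs 44 h and 20 h vs 92 h.

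In 44 h vs 68 h replicate 4 stood apart for AREG (0.786; log2 ratio 2.22, others -3.64 to -2.39), ADAMTS1 (0.735; 2.54, others -2.77 to -1.36), IGF2 (0.705; 5.29, others -6.26 to -2.85), KLF4 (0.662; 2.06, others -4.13 to -2.04), HSP90B1 (0.711; -0.42, others 0.40 to 0.73) and the mean of the matrix list (0.643; 0.68, others -1.35 to -0.63). Replicate 5 stood apart for STC1 (0.652; 1.87, others -3.07 to -1.35), BTG4 (0.889; 1.41, others -0.07 to 0.09) and FIGLA (0.643; 0.91, others -0.18 to 0.21), and replicate 2 for HBA (0.671; -1.90, others -0.43 to 0.30). In 44 h vs 92 h it was replicate 6 for THBS1 (0.658; 3.65, others -0.28 to 1.07) and replicate 5 for BTG4 (0.873; 1.17, others -0.04 to 0.11). Of these arrays, replicates 4 and 5 of 44 h vs 68 h and replicate 6 of 44 h vs 92 h are among the 7 whose labelled pair of hours did not have the highest r (-0.54, 0.49 and 0.72 against 0.71, 0.76 and 0.85). In 68 h vs 92 h it was replicate 3 for SCARB1 (0.669; -0.65, others -0.36 to -0.22) and CLDN5 (0.738; 0.56, others 0.27 to 0.34) and replicate 4 for NDUFV2 (0.639; -1.05, others -0.70 to -0.50). In 20 h vs 68 h it was replicate 4 for KDR (0.722; 0.50, others 1.49 to 1.87) and replicate 6 for OOEP (0.669; 0.48, others -0.04 to 0.13).

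The first pattern is the 10 channels, on 2 slides, that were nearest to hours other than their label. Poor hybridisation is argued against by their median correlation with the nearest channel, 0.71, against 0.77 (SD 0.09) for the channels of the other 4 comparisons. RNA of 44 h unlike the other RNA of 44 h is argued against as the whole cause, since 6 of the 10 channels are labelled with another hour. An exchange of the labels of the 2 slides may be the explanation: of the 10 channels whose label it would change, 10 were nearest to the hours on the other label. The exchange stays a hypothesis, found and tested on the same data, and no label was changed. No biological explanation was tested.

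The second pattern is that markers of other cells were higher at 44 h than at 20 h. A lower share of granulosa cells, raising every other cell type alike, cannot be told apart from a change in single cell types. The medians of the 5 lists ranged from 0.00 (oocyte) to 0.74 (theca and stroma), and this difference of 0.74 was under the pooled SD of their members, 1.11. A lower share also cannot be told apart from other causes of the fall of the cell cycle genes. By medians the follicular growth list, also of granulosa cells, lay 0.65 above the cell cycle list (-0.14 against -0.79), more than the SD of its members, 0.49, but by means it lay 0.43 above (-0.37 against -0.80), less than that SD. Among the 19 members above background at 20 h the differences were 0.63 and 0.40 (SD 0.48). By each of these measures the follicular growth list fell less than the cell cycle list. The SD of single members is a wide yardstick for list averages, so both tests could hardly decide. The SE of the follicular growth mean was 0.11, but members of a list are not independent replicates. Mean log2 intensities at 20 and 44 h were 8.03 and 13.62 for COL3A1, 8.02 and 12.95 for OGN and 11.70 and 12.77 for ACTA2, of theca and stroma, and 8.80 and 11.22 for CD53, of leukocytes; the leukocyte marker LYZ had a mean of 10.76 over all arrays. Of the lists, 13 of 18 theca and stroma, 17 of 26 leukocyte and 8 of 14 endothelial markers were above background in at least 9 of 18 channels at 20 h already, and 0, 1 and 0 are held by another list; a change of the granulosa cells themselves with time stays open, untested.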

How the results depend on the processing

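The 24 arrays alone, the values through 20 h, the partners chosen by similarity (leave-one-out among them) and the fits to 1 slide were tests chosen only after the result was seen. The cell cycle list of 44 h vs 68 h turned from 0.16 as labelled to -0.25 through 20 h, past the threshold in both (adjusted p = 0.574 and 0.89 with an estimated correlation), and its cholesterol synthesis list from 0.30 to -0.03, no longer past it. With slide as a fixed block the follicular growth list of 20 h vs 44 h turned from -0.14 to 0.18 and the ribosomal protein list of 44 h vs 68 h from 0.04 to -0.04. The former is then estimated through arrays of 20 h vs 68 h on the same slides and the latter from 1 slide. Neither turn shows an effect of slide. Of the alternatives set in advance, the authors' values were not run, as 35 of their 36 columns were closest to another array. Aquantile moves nothing by construction, as it leaves the ratio within an array as it was. No paired analysis was possible because the labels number arrays and not RNA samples. Dye-swap partners inferred from the channels (mean r 0.71 against 0.48 for the next arrangement in 20 h vs 44 h, 0.57 against 0.34 in 68 h vs 92 h and 0.77 against 0.52 in 20 h vs 68 h) were fitted as an alternative.

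Counts of probes past the threshold stayed within 1.5 times under no background correction, no filter and median centring in the 6 comparisons as labelled. Under other settings they moved, and the cause was not tested except where named. The 36 arrays unaveraged gave 3116 (20 h vs 44 h) and 5152 (68 h vs 92 h). The own 3 averages, with 2 residual degrees of freedom, gave 0 and 0 in limma in these 2 comparisons (5124 and 7661 at an unadjusted p under 0.05 in the pooled fit) and 1930 in 20 h vs 68 h. The network gave 8404 (20 h vs 44 h), 1660 (44 h vs 68 h), 6381 (68 h vs 92 h), 10409 (20 h vs 68 h) and 2579 (44 h vs 92 h). Slide as a random block gave 9683 (20 h vs 68 h; correlation within slide 0.175) and as a fixed block 250 (20 h vs 44 h) and 294 (68 h vs 92 h). The highest of 100 random arrangements, which need not pass in the other arrangements, gave 5010 (20 h vs 44 h), 743 (44 h vs 68 h), 7151 (68 h vs 92 h), 10224 (20 h vs 68 h) and 123 (44 h vs 92 h). An absolute log2 ratio of at least 1 left 567 (20 h vs 44 h), 584 (68 h vs 92 h), 1554 (20 h vs 68 h) and 2476 (20 h vs 92 h), a stricter rule. Partners chosen by similarity gave 962 (20 h vs 44 h); there 49 named genes were no longer past the threshold, 35 of them in 20 h vs 44 h, 6 list results were newly past it and 0 lists were lost. Leave-one-out in that arrangement gave 153 and 64 without replicate 2 or 3 of 20 h vs 44 h, 815, 365 and 1933 without replicate 4, 5 or 6 of 68 h vs 92 h, 3119 and 1527 without replicate 3 or 5 of 20 h vs 68 h, and 5689 and 5435 without replicate 1 or 3 of 20 h vs 92 h. The 3 arrays of 1 slide gave 0 in limma (6086 at an unadjusted p under 0.05) and 1024 in 20 h vs 44 h, 1928 in 68 h vs 92 h and 1443 in 44 h vs 92 h, each with a single dye orientation and 2 residual degrees of freedom.

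Leaving out 1 array with its partner left 2 averages, whose spread was pooled with that of the other comparisons. Without replicate 2, 3 or 4 the counts in 20 h vs 44 h were 338, 203 and 662. Without replicate 4, 5 or 6 of 68 h vs 92 h they were 832, 5.3e+02 and 1223. Without replicate 1, 3 or 5 they were 3324, 2804 and 2411 in 20 h vs 68 h. Likewise, in 20 h vs 92 h they were 5249, 5138 and 5643. Through 20 h they ranged from 46 to 833 in 44 h vs 68 h (52 and 46 without replicate 2 or 3 of 20 h vs 44 h, 157 and 59 without replicate 3 or 5 of 20 h vs 68 h) and from 258 to 820 in 44 h vs 92 h (258 and 370 without replicate 2 or 3 of 20 h vs 44 h, 377, 305 and 274 without replicate 1, 3 or 5 of 20 h vs 92 h). Fewer averages are part of the construction of these settings.

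With an estimated correlation 0 lists passed in each of the 6 comparisons in limma. Through 20 h, median centring gave 146 probes (44 h vs 68 h) and 599 (44 h vs 92 h), and it left 88 and 115 probes shared by the rises and falls of 20 h vs 44 h and 68 h vs 92 h. Of log2 ratios of named genes, 336 in leave-one-out, 63 with median centring, 15 with no background correction and 20 with the 24 arrays alone were no longer past the threshold, and 1080, 537, 584 and 342 kept direction and side. Of list results, 5 with median centring, 2 with no filter, 1 with no background correction and 1 with the mean of all kept probes were no longer past it: the leukocyte list in 20 h vs 92 h (median centring, no filter, no background correction), steroidogenesis and matrix in 20 h vs 92 h and oxidative phosphorylation in 20 h vs 68 h and 44 h vs 92 h (median centring), cytokines in 68 h vs 92 h (no filter) and ribosomal proteins in 44 h vs 68 h (mean of all kept probes). Median centring moved the share of rises through 20 h from 398 up and 364 down to 103 and 43 (44 h vs 68 h) and from 576 and 421 to 475 and 124 (44 h vs 92 h). Newly past it were 4 list results and 7 named genes with the 24 arrays alone, 7 and 1 with median centring, 1 and 2 with no background correction, 3 lists with no filter and 2 with the mean of all kept probes. Signal over background limits the dim probes: a median of 66.7 percent of probes per channel was above background.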

Other observations

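The tests of the value table in this part were chosen only after the result was seen, and the splits were set before the data were examined.

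Each comparison was refitted on the other splits of its 6 arrays, 3 against 3. The 10 splits are too few for a share under 0.05. The orientations on the labels gave 1758 probes in 20 h vs 44 h (highest other split 0), 3232 in 68 h vs 92 h (0), 6293 in 20 h vs 68 h (0) and 8760 in 20 h vs 92 h (21), so that 1 of 10 splits gave as many in each. In limma they gave 0 in 44 h vs 68 h (highest other 5; 2184 at an unadjusted p under 0.05) and 0 in 44 h vs 92 h (0; 1180), where 10 of 10 gave as many.

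The columns of the deposited value table were closest to an array other than their own in 35 of 36 cases. Their correlation across probes with their closest array ranged from 0.94 to 1. A different normalization by the authors is argued against as the cause, since the lowest correlation with a closest array, 0.94, lay above the highest with a second array, 0.87. The columns may be listed in another order than the arrays: 36 different arrays were found as the closest of the 36 columns. Column medians lay between -0.036 and 0.013. No biological explanation was tested.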
